A study of Mus musculus with 12 samples.

How the data were processed

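Poly-A RNA from the gastrocnemius, a calf muscle, of 12 male mice was sequenced in paired ends, with 6 WT and 6 KO animals aged 4 months. Per the labels, the WT mice carried floxed Ank2 alleles without a Cre transgene, and the KO mice carried the same alleles with a Cre driver active in skeletal muscle. Per the labels' protocols, the groups were littermates that shared cages, and the RNA was made into NEBNext Ultra libraries with no step that marks strand. Each library is a separate mouse.

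The authors deposited 1 table of 24528 gene symbols with 1 value per library on a log2 scale. Neither its header nor the labels name the transformation. The submitters' processing notes name fastp, STAR, featureCounts and the genome build mm10, without versions. The aligner settings, gene annotation and normalization are not given in the sources used here. All 12 columns share 1 lowest value, at which 6474 genes stand in every library, and no value is whole. This is the shape of a variance-stabilizing transformation, in which log2 differences between low values are compressed. A difference of the deposited values therefore understates the fold change of a gene with few reads.

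The design fixed before the data were examined was a count test, or limma on log values if the table held normalized values. The table held no counts, so limma was used. The values were already logarithmic, so no second logarithm and no pseudocount was applied. Low genes were removed with estimated reads. For these, the closed-form transformation was inverted, and the smallest step between low values of each library was taken as 1 read. Between 86.2% and 91.9% of the low values of a library then fell within 0.1 of a whole number of reads. The estimated reads are therefore approximate, and they were used for the filter, for depth, for levels as a percent of the WT mean and in some alternatives, never in the main test. Estimated totals ran from 12282313 to 18708417 reads per library.

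Genes with at least 10 estimated reads in at least 6 libraries were tested, which kept 12217 genes. Each was fitted with limma 3.58.1 (R 4.3.3) on the deposited values with group as the only term, a trend of variance with level and robust moderation. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Changes are KO minus WT on the log2 scale of the deposited values, given with the standard error (SE) of the fit. Levels are mean ± SD over 6 mice per group. Single values were compared with an exact two-sided permutation test over all 924 assignments of 6 libraries to KO.

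Before the data were examined, 27 gene lists and 11 lists of cell type markers were fixed. Of these, 35 had at least 3 measured members and were tested with camera, which compares a list with the other genes, at a preset inter-gene correlation of 0.01. Its p-values were adjusted over the 35 lists. The alternatives were camera with the correlation estimated per list and fry, which tests whether the genes of a list move on balance in 1 direction. The median change of each list was ranked among 10000 random lists of its size, matched on level. The random lists do not carry the joint variation of related genes, so this rank can be extreme through a few libraries. The mitochondrially encoded genes were not analysed here, and the lymphocyte and neutrophil markers had too few members past the filter.

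The named genes followed a rule written beforehand. It took Ank2, Ank1 and Ank3, and the 12 largest rises and 12 largest falls among called genes. Those genes needed a mean log2 CPM of at least 1 (here from estimated reads), a symbol that is no gene model or pseudogene, and all 6 KO libraries on 1 side of the WT median. The rule also took the 5 smallest p-values under the same conditions, and up to 4 members of each described list. Of the called genes, 606 met those conditions. Positions, genomic spans and transcript lengths come from GENCODE release M21, which is on the build the submitters name. Symbols without an entry there numbered 230 among the tested genes.

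The fit was tested on simulated data of the 12217 genes with the real means and spreads. It recovered 82% of 100 genes changed by 0.5 and 98% of 100 genes changed by 1, with 7 false calls. The simulated genes varied independently, with the same spread in WT and KO. Joint variation of genes and unequal spread, both present in the real libraries, were not covered. Alternatives covered other tests, scalings, filters and thresholds, a block by replicate number, a correction for gene length and the omission of each library in turn. Estimated reads carry counting error, and PCR duplicates cannot be told from separate molecules.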

Results

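Gene expression was measured in bulk gastrocnemius muscle of 6 WT mice and 6 KO mice designed to lack ankyrin-B in skeletal muscle. Ankyrin-B, the product of Ank2, is an adaptor that links membrane proteins to the spectrin cytoskeleton. The comparison asks which transcripts differ in muscle between these genotypes. The table lists 24528 genes, of which 18054 lay above the floor in at least 1 library and 12217 passed the filter on low values. Estimated depth was 14140537 ± 1796495 reads in WT and 16179750 ± 1811189 in KO (SD, n = 6 each; exact permutation p = 0.0801). The distribution of values differed between the groups: the 95th percentile of the tested genes was 11.51 ± 0.03 in WT and 11.43 ± 0.08 in KO (SD, n = 6 each; exact permutation p = 0.0368). Genes above the floor numbered 14746 to 15056 in WT libraries, 14836 in KO 2 and 15256 to 15794 in the other KO libraries.

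Ank2 was lower in every KO library than in every WT library. Its deposited log2 value was 8.88 ± 0.35 in WT and 7.74 ± 0.19 in KO (SD, n = 6 each), a change of -1.15 (SE 0.14, limma adjusted p = 0.00088; exact permutation p = 0.00216, the smallest that 924 assignments can give). Put back to scaled reads, the KO level was 33.1% ± 7.12 of the WT mean, with KO libraries from 26.3% to 44.3% and WT libraries from 63.4% to 128%. Ank2 lies on the minus strand of chromosome 3 from 126921612 to 127499350 (mm10), and 98.3 to 475 estimated reads per library stood behind its values. The values cover the whole gene and all cells of the tissue, so they do not measure the deleted part in muscle fibres alone. The other ankyrin genes did not pass the test. Ank1, the ankyrin-R gene, gave 0.05 (SE 0.10, adjusted p = 0.762), and Ank3, the ankyrin-G gene, gave -0.10 (SE 0.11, adjusted p = 0.574), which became 0.07 after a correction for gene length.

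**Figure D1:**
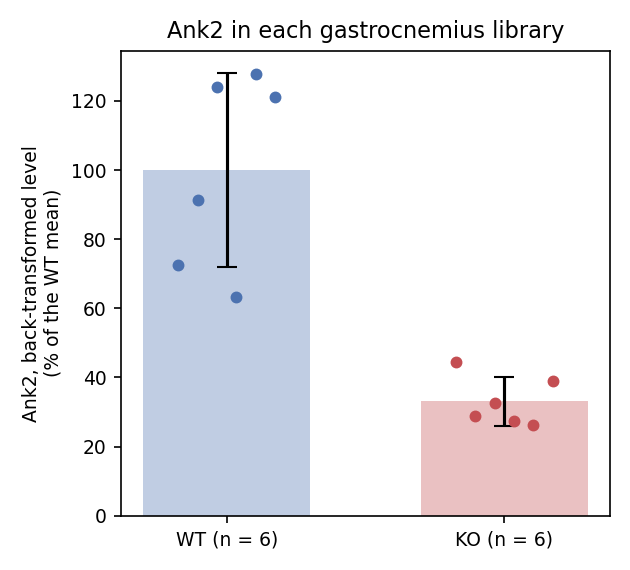
Ank2 level in each library as a percent of the WT mean, after inverting the transformation of the deposited values (points, libraries; bars, group mean; error bars, SD, n = 6 each). The KO libraries sit between 26.3% and 44.3%, all below the lowest WT library at 63.4%.

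The libraries separated by genotype along the first principal component of the 500 most variable tested genes, which held 50.8% of the variance. Its scores were -8.65 ± 2.62 in WT and 8.65 ± 7.00 in KO (SD, n = 6 each; exact permutation p = 0.00216). The KO libraries were more spread than the WT libraries. KO 2 lay nearest to WT, with a score of -2.32, next to WT 4 at -4.66. KO 1 lay farthest, at 16.1.

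**Figure D2:**
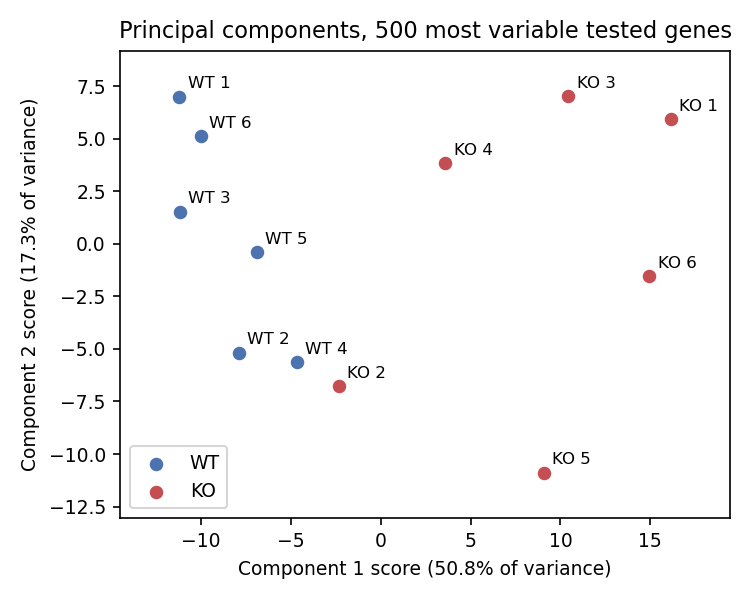
Scores of the 12 libraries on the first and second principal components of the 500 most variable tested genes (50.8% and 17.3% of the variance). Each point is a library; KO 2 lies at -2.32 on the first component, beside WT 4, while the other KO libraries lie at 3.60 or above.

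KO and WT muscle differed in 757 of the 12217 tested genes, of which 381 rose and 376 fell in KO (limma, Benjamini-Hochberg adjusted p at or under 0.05). Most changes were modest, with a median of 0.41 among the rises and -0.43 among the falls. At least 1.5-fold changes on the deposited scale numbered 87 up and 93 down. All 6 KO libraries lay on 1 side of the WT median in 690 of the 757 genes. An unadjusted p at or under 0.05 was reached by 3179 genes.

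The largest rises on the deposited scale included cardiac forms of contractile genes and a subunit of the acetylcholine receptor. Actc1, which encodes cardiac alpha-actin, rose by 2.53 (SE 0.63, adjusted p = 0.0437), from 11.07 ± 0.95 in WT to 13.60 ± 1.23 in KO (SD, n = 6 each). Tnnt2, cardiac troponin T, rose by 1.99 (SE 0.44, adjusted p = 0.032). Chrna1, the alpha subunit of the muscle acetylcholine receptor, rose by 1.96 (SE 0.30, adjusted p = 0.00713), from 8.23 ± 0.05 to 10.20 ± 0.76. Nmrk2, a nicotinamide riboside kinase of NAD synthesis, rose by 2.23 (SE 0.40, adjusted p = 0.0154). The remaining genes among the 12 largest rises were the metallothionein gene Mt3 (1.60), the imprinted noncoding RNA H19 (1.38), Fam174b (1.36), the stress-inducible Gadd45a (1.13), Gamt of creatine synthesis (1.09), the calcium channel beta subunit gene Cacnb4 (1.06), Maged2 (1.05) and the glycogen-binding protein gene Stbd1 (1.05).

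The largest falls on the deposited scale included the genes of an iron exporter, a potassium channel subunit and dystrophin. Mss51 fell by 2.29 (SE 0.51, adjusted p = 0.0341) and the serine protease gene Htra4 fell by 1.92 (SE 0.36, adjusted p = 0.0183). Slc40a1, which encodes the iron exporter ferroportin, fell by 1.39 (SE 0.24, adjusted p = 0.0116), and the potassium channel beta subunit gene Kcnab1 fell by 1.38 (SE 0.19, adjusted p = 0.0037). Dmd, the dystrophin gene on chromosome X from 82948870 to 85206141, fell by 1.18 (SE 0.19, adjusted p = 0.00669), from 10.61 ± 0.17 to 9.43 ± 0.50 (SD, n = 6 each). Cd28, known as a T-cell costimulatory receptor, had the smallest p of all tested genes (adjusted p = 1.98e-05) and fell by 1.27 (SE 0.11), from 7.46 ± 0.17 to 6.19 ± 0.24. The other large falls besides Ank2 were in Odf3l2 (-1.59), the ribosomal S6 kinase gene Rps6ka2 (-1.36), the tubulin polyglutamylase gene Ttll7 (-1.19), Odc1, the ornithine decarboxylase of polyamine synthesis (-1.14), and Fgfbp1 (-1.14). The deposited scale compresses changes at low levels, so the order differs after back-transformation to scaled reads. There the KO to WT ratio was 17.2 for Mt3, 16.8 for Fam174b, 10.4 for Tnnt2 and 6.04 for Actc1, and 0.108 for Cd28, 0.114 for Htra4 and 0.227 for Mss51. Among the 5 smallest p-values were also Snph, the syntaphilin gene (-0.94, adjusted p = 0.000239), and Ctnna3, an alpha-catenin gene (-0.59, adjusted p = 0.00088).

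**Figure D3:**
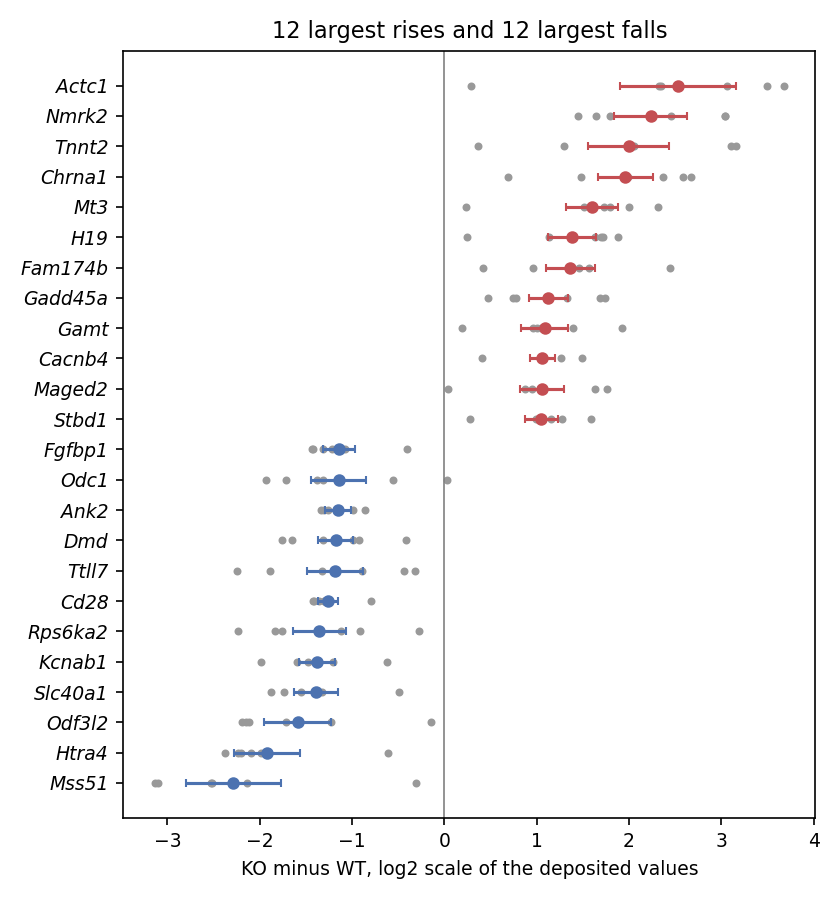
Change of the 12 genes with the largest rise and the 12 with the largest fall, KO minus WT on the log2 scale of the deposited values (coloured points, limma estimate; bars, SE; grey points, each KO library minus the WT mean). On this scale Actc1 heads the rises at 2.53 and Mss51 the falls at -2.29; in many of these genes 1 grey point lies apart from the rest, toward 0.

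The number of called genes rested on single libraries. It was 1515 without KO 2, and it was 367, 207, 205, 317 and 366 without WT 1, WT 2, WT 3, WT 5 and WT 6, and 272, 225 and 194 without KO 1, KO 3 and KO 6. Of the 28 genes named by size, p or family, Ank1 and Ank3 had no call to lose, and 11 of the others lost theirs without at least 1 library. Actc1 lost it without 10 of the 12 libraries (adjusted p up to 0.103), all but WT 5 and KO 2, and Odc1 without 10 (up to 0.106), all but KO 2 and KO 5. Ttll7 lost it without 9 (up to 0.104), all but KO 2, KO 4 and KO 5. Tnnt2, Gamt and Maged2 lost it without any 1 of WT 1, WT 2, WT 3, WT 5, WT 6, KO 1, KO 3 and KO 6 (up to 0.0729, 0.0835 and 0.0695). Mss51 and Odf3l2 lost it without any 1 of WT 1, WT 2, WT 3, WT 6, KO 1, KO 3 and KO 6 (up to 0.0809 and 0.0827), and Rps6ka2 without WT 2, WT 3, WT 5, KO 3 or KO 6 (up to 0.0625). Fam174b and Htra4 lost it without KO 6 (0.0521 and 0.0501). With limma-voom on estimated reads, Mt3 (adjusted p = 0.0761), Tnnt2 (0.0752) and Ttll7 (0.0502) were not called, and with the length correction Ttll7 (-1.06, adjusted p = 0.0534) and Odc1 (-1.20, adjusted p = 0.0521) were not, though their changes stayed about as large. Without the filter Ttll7 was not called (0.05, above the threshold before rounding), nor were Actc1 (0.0536), Odc1 (0.0536) and Ttll7 (0.0547) on scaled reads with a pseudocount of 0.1 and no filter. Actc1 encodes a protein nearly identical to that of Acta1 (0.11, adjusted p = 0.484; named after its values were seen). How reads shared by these genes, if any, were divided is not known. The genomic spans of Ank1, Ank2, Actc1, Nmrk2, Gadd45a, Cacnb4, Htra4, Kcnab1, Ctnna3 and Dmd overlap other annotated genes. Whether their exons overlap was not checked, and libraries without strand cannot separate reads of overlapping exons.

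The lists of genes induced in denervated and regenerating muscle were higher in KO, but their means in KO 2 lay within the WT range. In the denervation response, 4 of 14 measured genes rose and none fell, 8 with p-values adjusted over the list alone. They were Gadd45a, Ncam1, which encodes a neural cell adhesion molecule (0.36, adjusted p = 0.0231), the transcription factor gene Runx1 (0.63, adjusted p = 0.0402) and Myh8, the perinatal myosin (1.18, adjusted p = 0.0415). The list median was 0.47, and camera called the list higher (adjusted p = 4.06e-05; adjusted p = 0.393 with an estimated correlation). In myogenic regeneration, 6 of 14 genes rose and 1 fell, with 8 and 2 when adjusted over the list alone. Tnnt2 and Igf2, an insulin-like growth factor gene (0.90, adjusted p = 0.0344), rose, while the cadherin gene Cdh15 fell by 0.37 (adjusted p = 0.0342). Camera called this list higher too (adjusted p = 0.000795; adjusted p = 0.388 with an estimated correlation). Ncam1, Myh8 and other genes belong to both lists. The mean of the denervation list was 7.44 in KO 2, within the WT range of 7.43 to 7.67, against 8.10 or above in the other KO libraries. The mean of the regeneration list was 8.55 in KO 2, within the WT range of 8.51 to 8.63, against 9.15 to 9.34 in the others. Single members varied in KO 2. Gadd45a was 8.72 there, above the WT libraries at 8.03 to 8.48, while Actc1 was 11.36, within the WT range of 10.33 to 12.81.

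Among neuromuscular junction components, 5 of 15 genes rose and 1 fell, with 5 and 2 adjusted over the list alone. Besides Chrna1, the acetylcholinesterase gene Ache rose by 0.59 (adjusted p = 0.0201), as did the receptor subunit genes Chrnb1 (0.58, adjusted p = 0.0265) and Chrne (0.37, adjusted p = 0.0439). The gene that fell was Musk, a receptor tyrosine kinase gene of the junction (-0.62, adjusted p = 0.0498; named after its values were seen). The call was higher (camera adjusted p = 0.0238; adjusted p = 0.418 with an estimated correlation), with a median of 0.11. The list mean of KO 2 was 8.597, at the upper end of the WT range of 8.470 to 8.599, against 8.708 to 8.975 in the other KO libraries. Its Chrna1 value of 8.92 lay above the WT libraries at 8.17 to 8.30, so KO 2 shared that rise in weaker form.

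The lists of p53 targets, the integrated stress response and the oxidative stress response were higher, while those of endoplasmic reticulum chaperones (camera adjusted p = 0.477) and cytosolic heat-shock proteins (0.937) were not called. Of 14 p53 target genes, 2 rose and none fell, the same counts when adjusted over the list alone. They were Gadd45a, shared with the denervation list, and the cell-cycle inhibitor gene Cdkn1a (0.90, adjusted p = 0.0285). The list median was 0.20 (camera adjusted p = 0.00154; adjusted p = 0.358 with an estimated correlation). In the integrated stress response, 3 of 21 genes rose and none fell, with 4 adjusted over the list alone. They were the serine synthesis genes Psat1 (0.82, adjusted p = 0.0309) and Psph (0.32, adjusted p = 0.0277) and the proline synthesis gene Pycr1 (0.30, adjusted p = 0.0342). The call was higher with a median of 0.06 (camera adjusted p = 0.0273; adjusted p = 0.393 with an estimated correlation). It ended after a correction for gene length (adjusted p = 0.236) and without WT 2 or WT 4 (0.0639 and 0.0646). In the oxidative stress response, 4 of 23 genes rose and none fell, with 5 adjusted over the list alone. Nqo1 rose by 0.65 (adjusted p = 0.00437), Gpx1 by 0.58 (adjusted p = 0.0121), Txn1 by 0.44 (adjusted p = 0.0352) and Srxn1 by 0.35 (adjusted p = 0.0376); all encode antioxidant enzymes or proteins. The median was 0.03 (camera adjusted p = 0.0267; adjusted p = 0.393 with an estimated correlation), and the call ended with the length correction (adjusted p = 0.064) and without WT 3 or WT 4 (0.0508 and 0.0646). The mean of this list in KO 2 was 9.356, inside the WT range of 9.252 to 9.407, against 9.498 to 9.723 in the other KO libraries.

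Slow-fibre contractile genes were lower as a list, but no single member passed the test. Their median was -1.32, below all 10000 random lists, and 12 of 14 estimates were negative. That rank ignores their joint variation within groups (mean pairwise correlation 0.694). The estimates with the smallest p were those of the slow light chain gene Myl2 (-2.66, SE 0.83, adjusted p = 0.0835), Myh7b (-1.05, SE 0.38, adjusted p = 0.116), the slow calcium pump gene Atp2a2 (-1.29, SE 0.47, adjusted p = 0.119) and the slow myosin gene Myh7 (-3.37, SE 1.25, adjusted p = 0.128). Adjusted over the list alone, the count was also 0. The call was lower (camera adjusted p = 0.00154; adjusted p = 0.641 with an estimated correlation). The mean of the list was 10.59 ± 0.92 in WT and 9.23 ± 1.03 in KO (SD, n = 6 each; exact permutation p = 0.039), and the Myh7 value ran from 11.02 to 14.27 in WT and from 5.57, the floor, to 12.67 in KO. Fast-fibre genes gave 1 fall among 14, the kinase gene Mylk2 (-0.59, adjusted p = 0.0244), and 1 fall adjusted over the list alone (camera adjusted p = 0.925). Their median of -0.01 and mean of -0.10 were negative, while the direction of camera was upward.

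Camera called several lists of metabolism and protein degradation lower. None of the 24 genes of fatty acid uptake and oxidation passed the test, over all genes or adjusted over the list alone. Their median was -0.21, and the fatty acid transporter gene Cd36 gave -0.61 (adjusted p = 0.0506). The list call was lower (camera adjusted p = 0.0044; adjusted p = 0.701 with an estimated correlation), but the list means overlapped, from 10.29 to 10.98 in WT and from 10.26 to 10.73 in KO (exact permutation p = 0.177). Of 19 genes of mitochondrial biogenesis and dynamics, 1 fell by either adjustment, including that adjusted over the list alone. It was Fundc1, a mitophagy receptor gene (-0.29, adjusted p = 0.0374; list camera adjusted p = 0.0238; adjusted p = 0.641 with an estimated correlation). Of 19 genes of muscle atrophy and ubiquitin ligases, 1 fell and none rose, with 2 falls adjusted over the list alone. Trim63, the ubiquitin ligase MuRF1, fell by 0.44 (adjusted p = 0.0115), and the myostatin gene Mstn gave -0.99 (adjusted p = 0.0545). The list call was lower (camera adjusted p = 0.0238; adjusted p = 0.623 with an estimated correlation). In lipid synthesis, 1 of 16 genes fell, the desaturase gene Scd1 (-0.69, adjusted p = 0.0364), with 5 falls and 1 rise adjusted over the list alone. Camera did not call that list (adjusted p = 0.0984), whereas fry called it lower (adjusted p = 0.0418).

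In membrane excitation and calcium handling, 3 of 29 genes fell and 1 rose, with 4 and 2 adjusted over the list alone. The inositol trisphosphate receptor gene Itpr1 fell by 0.99 (adjusted p = 0.00851), the calcium channel subunit gene Cacna2d1 by 0.66 (adjusted p = 0.0192) and the triadin gene Trdn by 0.35 (adjusted p = 0.0358), while the sodium-calcium exchanger gene Slc8a3 rose by 0.39 (adjusted p = 0.0349). Of the 29 estimates, 20 were negative, but the largest went the other way without passing. It was that of Sln (2.71, SE 0.83, limma adjusted p = 0.0806, named after its values were seen). The list call was lower (camera adjusted p = 0.0273, and 0.64 with an estimated correlation) and ended without WT 4 or KO 3 (0.0752 and 0.055). Of 24 genes of ankyrins, spectrins and the dystrophin complex other than Ank2, Dmd alone fell, also when adjusted over the list alone, and camera did not call the list (adjusted p = 0.0984).

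Of the cell type markers, camera called those of vessels, which were lower. Of 10 endothelial markers, Flt1, a VEGF receptor gene, fell by 0.50 (adjusted p = 0.0347), with 3 falls adjusted over the list alone. The call was lower (camera adjusted p = 0.0405; adjusted p = 0.641 with an estimated correlation), but it ended with the length correction (adjusted p = 0.109) and without any 1 of WT 1, WT 3, WT 6, KO 2, KO 4, KO 5 and KO 6 (0.0597 to 0.103). The exact permutation p of the list mean was 0.0628. Of 10 smooth muscle and pericyte markers, the smooth muscle myosin gene Myh11 fell by 0.54 (adjusted p = 0.0418), with 4 falls adjusted over the list alone (camera adjusted p = 0.0238; adjusted p = 0.418 with an estimated correlation). Macrophage markers had 0 calls among 9 (median 0.22, camera adjusted p = 0.179; 0 adjusted over the list alone). No marker passed among 10 of fibro-adipogenic progenitors (adjusted p = 0.782), 10 of Schwann cells (0.925), 8 of tenocytes (0.934) and 5 of erythroid cells (0.277), nor adjusted over the list alone. Some of these lists were called in other settings: macrophage markers without WT 5 (camera adjusted p = 0.0105), Schwann cell markers without KO 1 (0.0211), and erythroid markers with the length correction (0.0279) and without KO 3 (0.0474). Satellite cell markers gave 1 rise, Sdc4 (0.27, adjusted p = 0.033), and 1 fall, Cdh15, among 7 (camera adjusted p = 0.399; the same counts adjusted over the list alone). Among 5 adipocyte markers, the carbonic anhydrase gene Car3 rose by 0.73 (adjusted p = 0.0256), and Adipoq fell by 0.34 (adjusted p = 0.0429), with 1 rise and 3 falls adjusted over the list alone (camera adjusted p = 0.451).

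**Figure D4:**
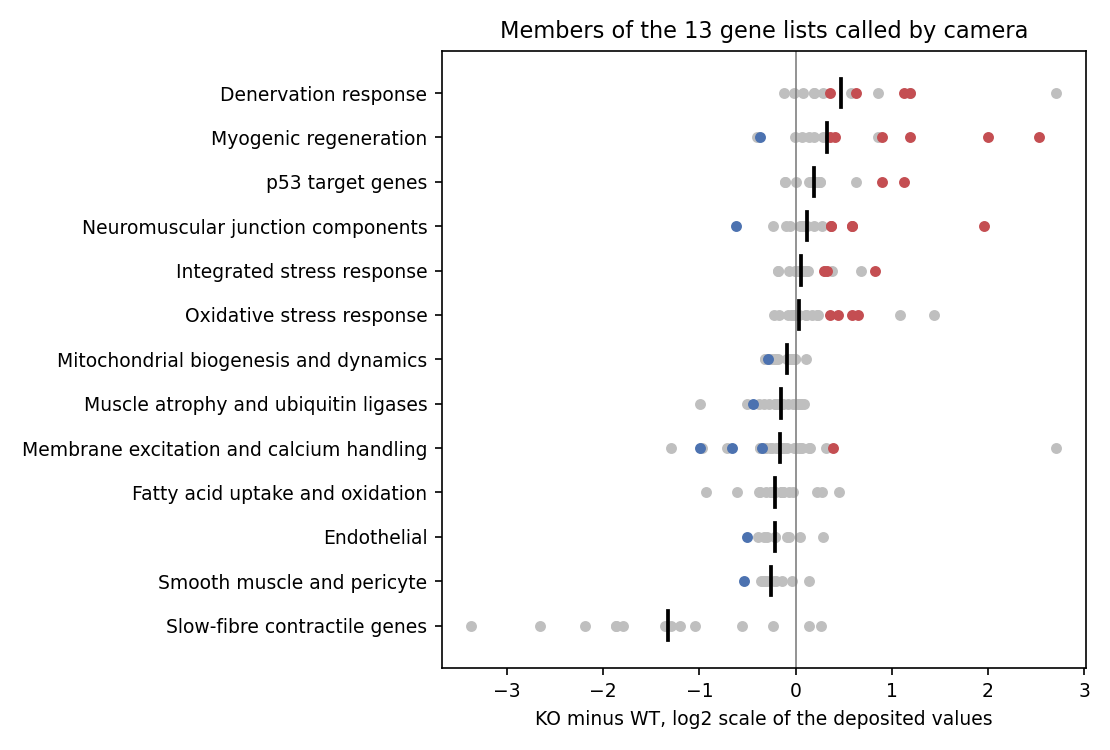
Change of each member of the 13 gene lists called by camera, KO minus WT on the log2 scale of the deposited values (grey points, genes that did not pass; red and blue points, genes that rose or fell; black lines, list medians). Medians run from 0.47 in the denervation response to -1.32 in slow-fibre genes, where every point is grey.

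Camera thus called 13 of 35 lists, 6 higher and 7 lower; with an estimated correlation it called 0 (smallest adjusted p = 0.358), and fry called 7. Fry kept the 6 higher calls, added lipid synthesis as lower, and kept none of the 7 lower calls. Its adjusted p was 0.181 for slow-fibre genes, 0.224 for fatty acid uptake and oxidation, 0.0695 for membrane excitation, 0.0695 for mitochondrial biogenesis, 0.0638 for muscle atrophy, 0.142 for endothelial markers and 0.06 for smooth muscle markers. Among 10000 random lists of matched size and level, the medians of the integrated stress response (percentile 92.4), the oxidative stress response (91.3) and mitochondrial biogenesis (18.3) did not stand apart. Those of the other called lists lay at percentile 99.4 or above when higher and 2.08 or below when lower. Lists that camera did not call reached such ranks too, among them macrophage markers (99.96), extracellular matrix (99.88) and lipid synthesis (0). The rank therefore did not separate called from uncalled lists. The 13 calls were not more than other splits of the libraries can give, since 12 of 100 splits, the real one included, gave at least as many. A split with 3 WT libraries on each side called 15 lists and 0 genes. A camera call of a single list at the preset correlation can therefore arise without a split by genotype. Camera called none of the lists of endoplasmic reticulum chaperones (adjusted p = 0.477), cytosolic heat-shock proteins (0.937), immediate early genes (0.776), cytokines and NF-kappaB targets (0.477), the interferon response (0.323), autophagy and lysosome (0.58) or the clock (0.344). The heat-shock list held 1 rise, Hspb3 (0.74, adjusted p = 0.0133), and 2 falls, Dnajb4 (-0.43, adjusted p = 0.0217) and Hsph1 (-0.45, adjusted p = 0.0437), with 3 and 3 adjusted over the list alone. Of the polyamine and amino-acid list, Odc1 alone fell among 17 genes, with 2 rises and 4 falls adjusted over the list alone (adjusted p = 0.477). Lists of glycolysis (adjusted p = 0.179), insulin signalling (0.0572), nuclear-encoded oxidative phosphorylation (0.455) and extracellular matrix (0.133) were not called either. The length correction brought calls of oxidative phosphorylation (0.00938) and extracellular matrix (0.0229). Extracellular matrix was also called without WT 5, KO 2 or KO 5 (0.00859 to 0.0345), insulin signalling without WT 1, WT 4, KO 4 or KO 5 (0.0273 to 0.0431), and glycolysis without WT 4 (0.036).

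The changes were related to gene length. Across 11987 genes with a known length, which are not independent replicates, the change had a Spearman correlation of -0.343 with genomic span. Of genes shorter than 10000 bases, 141 rose and 36 fell; of genes longer than 100000 bases, 30 rose and 120 fell, Dmd and Ank2 among them. The slope of each library's values on span was 0.061 ± 0.070 log2 units per unit of log10 span in WT and -0.061 ± 0.084 in KO (SD, n = 6 each; exact permutation p = 0.0303). The slopes overlapped, from -0.034 to 0.127 in WT and from -0.175 to 0.045 in KO. After a correction of each library for this trend, chosen after the data were seen, 518 of the 736 called genes with a known length stayed called, 298 higher and 220 lower.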

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

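The tests of single-library length slopes, of the calls left after the length correction, of Ank2 level against distance from WT and of the joint variation of slow-fibre genes were chosen after those results had been seen.

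Within groups of 6, a library stood apart from the rest of its group in 14 of 226 sets of values, where chance gives about 11.3. The figure given for each is the gap to the nearest library divided by the range of the group, with a limit of 0.625. KO 2 was the library apart in 6 of them. It was the highest KO library for Mss51 (0.649), Htra4 (0.779), Cd28 (0.810) and Fgfbp1 (0.653), and the lowest for Nqo1 (0.655) and for the mean of the myogenic regeneration list (0.759). Among WT libraries, WT 4 was the highest for Gamt (0.794) and Maged2 (0.778), WT 5 the lowest for Tnnt2 (0.690), WT 6 the lowest for Cacnb4 (0.678) and WT 1 the lowest for Ache (0.630). KO 6 was the highest for Pycr1 (0.681) and for the mean of the endoplasmic reticulum chaperones (0.628), and KO 1 the highest for the mean of the Schwann cell markers (0.630).

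KO 2 differed from WT by less than the other KO libraries did: with each library scored along the genes called without that library, its change was 0.202 of the change fitted in the others, against 0.682 to 1.44 in the other KO libraries and -0.054 to 0.342 in WT. The Ank2 values gave no sign of more Ank2 RNA left in KO 2. Its value lay 0.13 below the mean of the other 5 KO libraries, within their spread (value -0.13, spread of those libraries 0.21 SD). Across the KO libraries, Ank2 and the size of the change had a Spearman correlation of 0.771, so those nearer to WT tended to hold less Ank2. These values cover the whole gene and all cells, so they cannot tell whether intact Ank2 was left in the fibres of KO 2. WT RNA mixed into KO 2 would bring Ank2 back too, but its Ank2 went -0.076 of the way back to WT while the median of 1514 other called genes went 0.769. The length trend was not the source either, as the score was 0.182 after its correction, below the lowest other KO library at 0.717. KO 2 also had the fewest estimated reads of the KO libraries, 13404280 against 15354129 to 18708417, and depth was not tested as a source. A difference among the animals stays open as a hypothesis, which was not tested because the labels give the KO mice no trait that sets them apart.

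Long genes were lower and short genes higher in KO. With GC content held fixed, the correlation across genes of the change with span was still -0.294, which argues against GC content as the whole cause. Shorter mature RNA, as from RNA integrity or library preparation, stays open: the correlation with mature length at fixed span was -0.145, and with span at fixed mature length -0.199. Library slopes overlapped between the groups but differed on average (exact permutation p = 0.0303), so a trend of single libraries cannot be told apart from one that goes with genotype in 12 libraries. The trend was not the whole cause of the called genes, because 70.4% of them stayed called after it was removed.

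Slow-fibre genes were called lower in KO as a list, but the call ended with an estimated correlation (adjusted p = 0.641) and with fry (0.181). They varied together within groups, with a mean pairwise correlation of 0.694, and their mean level ran from 9.56 to 11.95 in WT and from 7.85 to 10.49 in KO. A varying share of slow muscle in the pieces taken may therefore account for part or all of it, and cannot be told apart from an effect of genotype, because the exact permutation p between groups was 0.039 while the ranges overlapped. The length trend does not account for it, since the median after its correction was -1.28.

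The count of called genes was set against 100 of the 462 ways to split the 12 libraries into equal groups, the real split included. Only the real split, 1 of 100, gave 757 genes or more, a share under the 0.05 level among the splits drawn. The remaining splits were not run. The highest other split gave 739; it exchanged KO 2 with WT 4, although Ank2 stood at 28.9% of the WT mean in KO 2 and 63.4% in WT 4, on the side of their labels. For the gene lists, 12 of 100 splits gave the real 13 calls or more, with up to 16 in another split, so chance is not excluded for the number of lists. Since splits that mixed the genotypes called lists too, camera at the preset correlation does not exclude chance for a single list either.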

How the results depend on the processing

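The length correction, its combination with the block, the residual component, quantile normalization and the scale of reads plus 1 were chosen after the data were seen. Ank2 stayed called and lower under all 26 alternatives run (adjusted p 0.000173 to 0.00423). Its change was -0.98 to -1.25 on the deposited scale and -1.54 to -1.62 on the log2 scale of estimated or scaled reads, so the wider range reflects the change of scale. Median-of-ratios size factors and scaled reads plus 1 both gave 696 calls and an Ank2 change of -1.56, so they are not separate checks. No called gene changed sign under any of the 26 alternatives. Ank3, never called, turned to 0.069 with the length correction, with or without the block. The 757 calls (381 higher, 376 lower) became 1215 (572 and 643) with limma-voom sample quality weights, 2470 (987 and 1483; 40.0% higher against 50.3%) with the first residual component as a covariate, 76 (39 and 37) at an adjusted p of 0.01, and 180 (87 and 93) with at least a 1.5-fold change. Leaving out 1 library gave 194 to 1515 calls, 106 to 682 higher and 88 to 833 lower, and 11 to 15 called lists. A tighter threshold lowers the count by construction. The count rose without WT 4 (878), KO 2 (1515), KO 4 (965) or KO 5 (785) and fell without each other library; for these counts, the quality weights and the residual component the cause was not tested. The other scalings, filters and tests gave 634 to 862 calls. The share of higher calls was above the main 50.3% with the length correction (376 higher, 258 lower; 59.3%), a pseudocount of 0.1 (424 and 296; 58.9%), quantile normalization (495 and 367; 57.4%) and no filter (468 and 349; 57.3%), so the even balance depends on the processing. List calls numbered 0 with an estimated correlation and 7 with fry. The called lists lost most often were endothelial markers. Ank2 had 98.3 estimated reads in its lowest library.

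Replicate numbers are shared by the groups, but no label ties them to a litter or cage, and 2 of 6 same-numbered pairs had correlated deviations above 0.1 (-0.36 to 0.29), with 2 of 6 KO libraries closest to their own number. A replicate block gave 813 calls (357 higher, 456 lower; 615 shared), 686 with the length correction added, and it ended the calls of Actc1, Tnnt2, Ttll7 and Odc1, and with the length correction also those of Gamt (0.0568) and Maged2 (0.0614); Ank2 kept -1.15 (adjusted p = 0.0019) and 13 lists stayed called. Not run were the DESeq2 and svaseq alternatives, which need counts, and the omission of mitochondrially encoded genes, which were not analysed here.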

Other observations

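The lists of imprinted and ribosomal protein genes, and the test of imprinted genes, were chosen after values had been seen.

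Several imprinted genes rose in KO. At the H19 locus, H19 (1.38) and Igf2 (0.90) rose, as did Cdkn1c, a cell-cycle inhibitor gene nearby (0.62, SE 0.16, limma adjusted p = 0.0407). In the Dlk1-Dio3 cluster, the noncoding RNAs Rian (0.65, SE 0.13, adjusted p = 0.0133) and Mirg (0.25, SE 0.07, adjusted p = 0.0494) rose, and Meg3 gave 0.51 (SE 0.15, adjusted p = 0.0527). Of 21 measured imprinted genes, 5 rose and none fell, and the same 5 were called after the length correction. The hypothesis that imprinted genes rise as a group was first tested on all 21, whose mean level differed (exact permutation p = 0.0108), while camera gave p = 0.000254 at the preset and p = 0.0541 with an estimated correlation. Because 10 of them had been looked up before the list was written, the test was then changed, after that result was seen, to the other 11. Their mean level was 8.09 ± 0.05 in WT and 8.14 ± 0.09 in KO (SD, n = 6 each; exact permutation p = 0.223). Whether the rise is limited to the loci named above is left open. Of all 21 genes, 14 had positive estimates, but the 21 include the genes looked up before. Of the 11 not looked up, 5 had positive estimates and 0 were called, with a median of -0.001. Among all 21, Peg3 (0.50, limma adjusted p = 0.157) and Mest (0.30, limma adjusted p = 0.105) lie elsewhere, had positive estimates and did not pass.

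Ribosomal protein genes, whose list was corrected by a few symbols after a first run, had positive estimates in 81 of 82 cases, with a median of 0.27, but 8 rose past the threshold. Their mean level was 11.09 ± 0.17 in WT and 11.36 ± 0.15 in KO (SD, n = 6 each; exact permutation p = 0.0216). Camera gave p = 6.27e-22 at the preset correlation but p = 0.133 with an estimated correlation. These genes are short, with a median span of 3266 bases, and many have pseudogene copies that can share reads. The length correction lowered the median change to 0.16, with 75 of 82 estimates positive. It left 5 genes called higher, and Rps27rt was then called lower (-0.22, limma adjusted p = 0.0434). The exact permutation p of the mean level became 0.00866. The length trend could account for part of the difference, and how much is open.

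No concentration of called genes around Ank2 was detected. Within 5000000 bases of it, 3 of 36 tested genes were called (Egf, Snhg8 and 6330410L21Rik, named after their values were seen), against 732 of 11950 elsewhere (Fisher's exact test, two-sided, p = 0.483). Nor did they gather in 1 stretch of the genome. The largest number among 20 neighbouring tested genes was 6, on chromosome 2 around Actc1, and shuffled calls reached that number with a permutation p of 0.921.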
